A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

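The data were native elongating transcript sequencing (NET-seq) libraries of RNA polymerase I (Pol I) from budding yeast, Saccharomyces cerevisiae. In this assay the polymerase is immunoprecipitated with the RNA it holds, and each read places the last nucleotide of an RNA at 1 position of the gene. Per the labels' protocols, cells were filtered and flash frozen, lysed in the cold, and RNA was extracted from the Pol I immunoprecipitate. A DNA linker carrying a unique molecular identifier (UMI) was ligated to the RNA 3′ ends before reverse transcription, circularisation and amplification. There were 9 libraries, 3 each from the wild type (WT), the rpa34Δ strain and the rpa49Δ strain, grouped by the titles in the labels.

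Per the submitters' processing notes, bcl2fastq 2.20.00, cutadapt 3.4, STAR 2.7.1a, SAMtools 1.6, bedtools 2.28.0 and R 4.0.2 were used with genome build R64. Their order, their settings, whether reads with the same UMI were counted once and how reads matching both copies of the gene in the build were placed are not given in the sources used here. The 2 deposited tables, 1 per deletion with the same WT columns in both, hold 1 row for each of the 6858 nucleotides of the 35S rRNA gene. The replicate columns the authors deposited are in reads per 1000000 (RPM). Each column summed to 1000000 from position 1 to the terminator element T1 at position 6739, and the 119 positions after T1 were scaled by the same factor. The deposited ratio is the mean of the deletion over the mean of WT. It was listed as exactly 100 at 1 position for rpa34Δ and 2 for rpa49Δ, for a reason not given in the sources used here. The p-value the authors deposited for each position is unadjusted and matched an unequal-variance test recomputed from the replicate columns to within 4.96e-08. Because the WT columns were identical and every library was scaled on its own total, the deletions were also compared with each other directly.

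Values in a library were whole multiples of 1 step, so whole reads could be recovered. Within a tolerance of 0.01 read, at least 99.956% of the values of every library were whole, and 10 of all 61722 values were not. Recovered depth ran from 1242139 to 5353045 reads per library, so that 1 read was worth 0.187 to 0.805 RPM. At 12 positions every library was listed at 0: positions 1, 6 and 8, and 3 adjacent nucleotides at the 3′ end of each mature rRNA (2499 to 2501, 3018 to 3020 and 6647 to 6649). Why these were 0 is not given in the sources used here.

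For this work each library was scaled to 1000000 reads over the whole gene and summed in 138 bins of 50 nt from the 5′ end. The last bin ends with the gene at position 6858 and is shorter than 50 nt, but was counted as a spacer bin like the others. Bins, and single positions with a mean of at least 10 RPM over the libraries compared, were tested on log2(RPM + 10) with limma 3.58.1 (lmFit and eBayes with trend, R 4.3.3), using the libraries of the compared groups alone. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 changes are on this scale, which understates the change of low positions. Measures with 1 value per library (shares of occupancy per region, at each base and within 10 nt of the ends of mature rRNA; the occupancy-weighted mean position; the Gini coefficient; the share in the highest 1% of positions) were compared by two-sided exact permutation tests. With 3 libraries against 3 an exact permutation test has 10 splits and cannot go below p = 0.1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Nothing in the labels says whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. Intervals on shares of reads are exact (Clopper-Pearson) at 95% and cover counting error only.

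On simulated data with known changes the position test, run on 6320 positions, called 84% of 1.5-fold and 100% of 2-fold changes in the simulation of rpa34Δ against WT, and 76% and 96% for rpa49Δ against WT. For rpa49Δ against rpa34Δ it called 76% and 92%. The test of 138 bins called all 5 bins changed 1.5-fold in each simulated comparison. Of 118 unchanged bins it called 6 for rpa34Δ against WT, 2 for rpa49Δ against WT and 0 for rpa49Δ against rpa34Δ, and 1 bin changed 1.2-fold was called in the wrong direction for rpa49Δ against WT. Every simulated group was drawn from the WT profile with the spread of the WT libraries. In each simulation 200 positions or 20 bins were changed, chosen so that the total stayed as it was. In the real comparisons more of the gene changed and the shares of regions shifted, so these rates may not carry over. As an added alternative edgeR 4.0.16 (quasi-likelihood test) was run on the recovered reads.

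Named items followed a rule set before the data were examined. They are every annotated region, for each comparison the 10 bins with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, the 3 single positions with the largest rise and the 3 with the largest fall by the same rule, and the 5 positions highest in WT. Alternatives set before the data were examined were other bin widths, pseudocounts, filters, scalings and variance models, the median position of a bin, a replicate block, and each library left out in turn. Scaling on spacer or mature rRNA reads alone, edgeR and thinning to equal depth were chosen after seeing the data. Positions are counted from the 5′ end of the gene. Gene names come from the RefSeq table of build R64. The deleted genes themselves lie outside the tables and were not analysed here.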

Results

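The study asked how Rpa49 affects the occupancy of Pol I, the enzyme that makes the 35S ribosomal RNA precursor. Rpa49 and Rpa34 form a heterodimer on the surface of Pol I that resembles the general factor TFIIF of Pol II, and yeast survives without either. NET-seq profiles were made from WT, rpa34Δ and rpa49Δ cells, with 3 libraries each. WT libraries held 4448068, 4857534 and 5353045 reads, rpa34Δ libraries 2654736, 3575357 and 3367436, and rpa49Δ libraries 1547073, 1568118 and 1242139. Occupancy is given in reads per 1000000 reads of the library over the gene (RPM). The gene is the RDN37-2 copy on the minus strand of chromosome XII, from 460712 to 467569 in build R64, so position 1 is nucleotide 467569 and coordinates decrease along the gene. It holds the 5′ external transcribed spacer ETS 1 (positions 1 to 700), 18S (701 to 2500), the internal spacer ITS 1 (2501 to 2861), 5.8S (2862 to 3019), ITS 2 (3020 to 3251), 25S (3252 to 6647) and the 3′ spacer ETS 2 (6648 to 6858). Spacers are cut from the precursor and degraded, whereas 18S, 5.8S and 25S become the RNA of ribosomes. Means are given ± SD over the 3 libraries of a group.

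In WT, RNA 3′ ends were denser in the mature rRNA sequences than in the spacers, with 169 ± 1.87 RPM per nucleotide against 63.5 ± 6.66 (n = 3). The spacers together held 9.55% ± 1.00 of occupancy, of which ETS 1 held 6.11% ± 0.846, ITS 1 1.51% ± 0.0711, ITS 2 1.23% ± 0.105 and ETS 2 0.707% ± 0.114. 25S held 55.8% ± 0.938, 18S 31.9% ± 0.130 and 5.8S 2.79% ± 0.0224. The position with the highest WT mean, at 2320 ± 229 RPM, was 6646, next to the 3′ end of 25S. It was followed by 102 in ETS 1 (2016 ± 334), 1031 in 18S (1844 ± 137), 6662 in ETS 2, which adjoins the residues annotated as cleaved by the endonuclease Rnt1 (1599 ± 390), and 2498 near the 3′ end of 18S (1449 ± 157). This ranking leaves out the positions listed as 0 in every library, among them those adjoining 6646 and 2498 on the 3′ side.

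**Figure D1:**
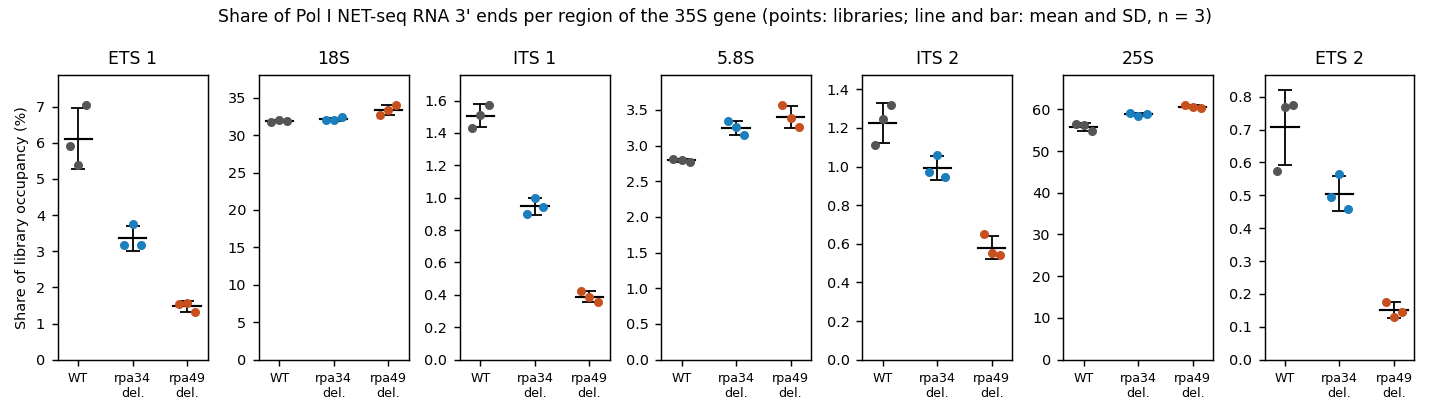
Share of each library's occupancy in each region of the 35S gene, in percent (y axes start at 0 and differ between regions), for WT, rpa34Δ and rpa49Δ; points are libraries, lines and bars the mean and SD of 3 libraries. In all 4 spacers (ETS 1, ITS 1, ITS 2 and ETS 2) the groups do not overlap, and the means run from WT through rpa34Δ to rpa49Δ, in ETS 1 from 6.11% to 3.36% and 1.47%.

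Loss of Rpa34 went with a smaller share of occupancy in the spacers and a larger share in 5.8S and 25S. Shares show the distribution along the gene and not the amount, so a gain in 1 part can follow from a fall in another. ETS 1 held 3.36% ± 0.341 of occupancy in rpa34Δ, 1.82 times less than in WT, ITS 1 0.946% ± 0.0510, ITS 2 0.993% ± 0.0602 and ETS 2 0.505% ± 0.0541 (n = 3). 5.8S held 3.25% ± 0.0979 and 25S 58.8% ± 0.383. In these 6 regions the libraries of both strains did not overlap (exact permutation p = 0.1, the smallest possible; 0.117 after adjustment over 7 regions). The share of 18S, 32.1% ± 0.233, did not separate from WT (exact permutation p = 0.3). Occupancy within 10 nt of the ends of mature rRNA was 2.15% ± 0.0476 against 1.74% ± 0.112 in WT (exact permutation p = 0.1). The difference of 0.406 points was 0.247 within 3 nt and 0.139 within 25 nt (exact permutation p = 0.2 for the latter), and each window holds the positions at the 3′ ends that were 0 in every library.

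Of 138 bins, 51 passed the threshold in rpa34Δ, 22 higher and 29 lower (limma, adjusted p under 0.05). All 7 bins of ITS 1, all 4 of ITS 2, 12 of 14 in ETS 1 and 2 of 5 in ETS 2 fell, and no spacer bin rose. Within ETS 1 the bins fell unequally. The bin from 51 to 100 fell by 2.48 on the log2 scale (SE 0.110, limma adjusted p = 4.95e-08), that from 451 to 500 fell by 2.27, and those starting at 251, 301 and 351 had log2 changes of -2.18, -1.97 and -1.33. The bins starting at 501, 551 and 401 had log2 changes of -0.88, -0.81 and -0.73, while the bin from 201 to 250 had a log2 change of -0.05 (SE 0.122, limma adjusted p = 0.786). Outside ETS 1 the largest falls were in ITS 1 at 2651 to 2700 (fell by 1.09) and in ETS 2 at 6701 to 6750 (fell by 0.88). The largest rise was in 25S at 6351 to 6400 (log2 change 0.98, SE 0.0759, limma adjusted p = 2.70e-06), and most of it lay at the single position 6399. Smaller rises, of 0.21 to 0.35, lay in 25S at bins starting at 5001, 5151, 5301 and 5901, in 5.8S at 2901, in 18S at 1251 and 2451, and in the bins that span the 3′ ends of 5.8S (3001) and 25S (6601). In the bin at 3001 the median position went the other way, with a log2 change of -0.50.

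The split between higher and lower bins in rpa34Δ depended on the scaling. With the median log2 bin value of each library set equal, 9 bins were higher and 33 lower, and without rpa34Δ replicate 1 the number of bins past the threshold was 27. With bins of 25 nt 97 passed, and with bins of 100 nt 28. Scaled on spacer reads alone, 13 of the 30 spacer bins rose and 7 fell, and the falls at 401, 551 and 6701 were no longer past the threshold (limma adjusted p = 0.897, 0.249 and 0.0741; over all alternatives from 7.39e-06 to 0.897, from 0.000295 to 0.249 and from 6.31e-05 to 0.0741). The falls at 301, 351, 2651 and 501 kept their call but shrank to -1.26, -0.62, -0.37 and -0.16. With the median position of the bin, that at 51 was -1.61 and that at 401 -1.34. Scaled on mature rRNA reads alone, 8 of 104 bins rose and 10 fell. The rises at 5151, 1251 and 6601 lost their call in 7, 6 and 5 alternatives, with limma adjusted p up to 0.147, 0.148 and 0.234. At 6351, 2451, 5001 and 5301 the call ended when the median position of the bin was used (limma adjusted p = 0.0954, 0.371, 0.311 and 0.463), and at 5301 also without WT replicate 1 (limma adjusted p = 0.0625). The size at 5301 was 0.19 without rpa34Δ replicate 3, and that at 1251 was 0.14 without WT replicate 1.

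At single-nucleotide resolution 2773 of 6425 positions passed the threshold in rpa34Δ, 1269 higher and 1504 lower. In the spacers 722 of 1104 positions fell and 80 rose; in mature rRNA 782 of 5321 fell and 1189 rose. Both splits depended on the scaling. Scaled on spacer reads alone, 400 spacer positions rose and 419 fell, and scaled on mature rRNA reads alone, 847 mature rRNA positions rose and 985 fell. With a minimum of 50 RPM over the whole gene, 1149 positions were higher and 918 lower. The 3 largest rises were at 138 in ETS 1, from 22.5 ± 5.24 RPM in WT to 605 ± 119 (log2 change 4.24, SE 0.140, limma adjusted p = 8.30e-11), at 6399 in 25S, from 383 ± 45.8 to 4265 ± 1031 (log2 change 3.42), and at 139, from 33.9 ± 9.03 to 152 ± 33.5 (log2 change 1.88, or 2.86 scaled on spacer reads). The 3 largest falls were all in ETS 1. Position 98 went from 1178 ± 215 to 39.3 ± 4.83 (fell by 4.58 on the log2 scale), 405 from 824 ± 102 to 32.5 ± 2.37 (fell by 4.29) and 292 from 560 ± 121 to 31.4 ± 2.284 (fell by 3.77). Of the highest WT positions, 102 fell by 2.53 to 342 ± 58.6, 1031 fell by 0.53 to 1270 ± 83.2 and 2498 rose to 2435 ± 251 (log2 change 0.75). Position 6662 fell by 0.46 to 1146 ± 181 (limma adjusted p = 0.0424), a call lost in 8 alternatives and turned to 0.26 when scaled on spacer reads. Position 6646, at 2585 ± 75.9, was not past the threshold (limma adjusted p = 0.353). In the authors' deposited table, 1402 positions were lower and 1075 higher at an unadjusted p under 0.05, of 6845 with a p-value. After Benjamini-Hochberg adjustment 508 of these p-values were under 0.05, against 2773 positions by limma, so the count depends strongly on the test.

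Loss of Rpa49 went with lower shares in every spacer and higher shares in 18S, 5.8S and 25S. ETS 1 held 1.47% ± 0.143 of occupancy, 4.15 times less than in WT, ITS 1 0.388% ± 0.0335 (3.88 times less), ITS 2 0.581% ± 0.0594 (2.11 times less) and ETS 2 0.151% ± 0.0232 (4.68 times less; n = 3). The share of 18S was 33.3% ± 0.694, that of 5.8S 3.402% ± 0.156 and that of 25S 60.7% ± 0.321. The libraries of both strains did not overlap in any of the 7 regions (exact permutation p = 0.1; 0.1 after adjustment). Occupancy within 10 nt of mature rRNA ends was 2.53% ± 0.0683 (exact permutation p = 0.1), a difference from WT of 0.788 points that was 0.433 within 3 nt and 0.256 within 25 nt.

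**Figure D2:**
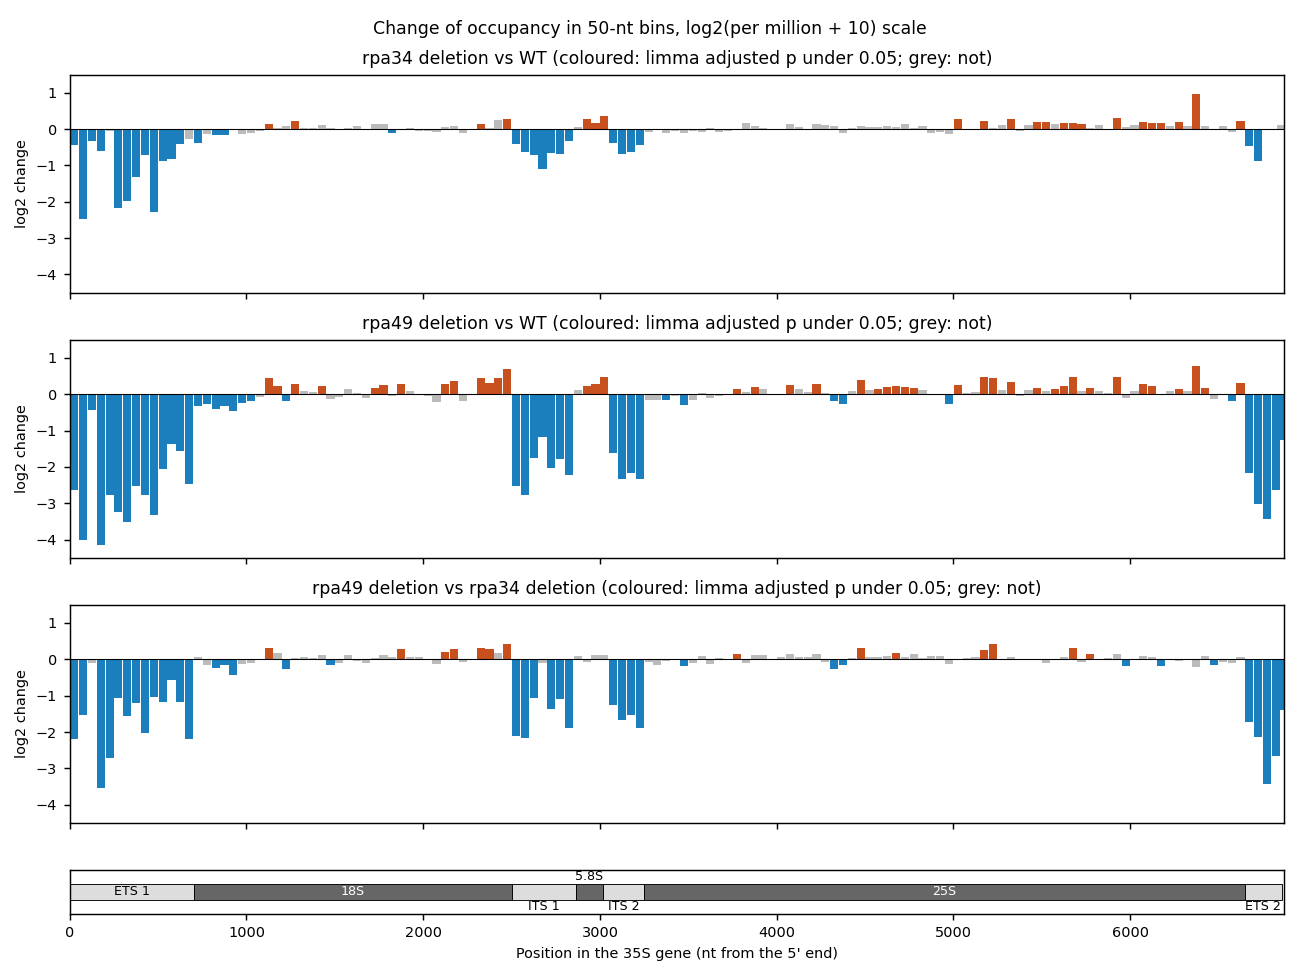
Log2 change of occupancy in each 50-nt bin along the 35S gene for the 3 comparisons (y axis log2 of occupancy RPM + 10; x axis position in nt; coloured bars passed a limma adjusted p of 0.05, orange up and blue down, grey bars did not), above a map of the regions. In rpa49Δ against WT all 30 spacer bins are blue, down to -4.15, and the bins of mature rRNA lie between -0.47 and 0.78.

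Of 138 bins, 86 passed the threshold in rpa49Δ, 42 higher and 44 lower. All 30 spacer bins fell, with log2 changes from -4.15 to -0.43. In ETS 1 the bin at 151 to 200 fell by 4.15 (SE 0.159, limma adjusted p = 8.03e-11), from 5754 ± 907 to 315 ± 51.5 RPM, and that at 51 to 100 fell by 4.03 (SE 0.135, limma adjusted p = 4.44e-11). The bins starting at 301, 451, 251, 201 and 401 had log2 changes of -3.52, -3.31, -3.23, -2.77 and -2.77. In ETS 2 the bin at 6751 to 6800, which lies past T1 and holds the binding site of Reb1 and Nsi1 next to T1, fell by 3.43, and that at 6701 to 6750 fell by 3.02. The former held 10 to 21 reads per rpa49Δ library. In ITS 1 the bin at 2551 to 2600 fell by 2.78.

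In mature rRNA 40 of 104 bins rose and 14 fell in rpa49Δ. The 10 largest rises included 6351 in 25S (log2 change 0.78, limma adjusted p = 0.00487), whose call ended with the median position of the bin (limma adjusted p = 0.390; from 5.97e-05 to 0.390 over all alternatives). Without rpa49Δ replicate 2 its log2 change was 0.44, since position 6399 in it was at 1149, 7637 and 2141 RPM in the 3 libraries. The bin at 2451, the last full bin of 18S, had a log2 change of 0.69 (SE 0.0938), or 0.26 with the median position, and that at 3001, which spans the 3′ end of 5.8S, 0.48, but -1.35 with the median position. The others were 5651, 5901, 5151, 5201 and 4451 in 25S and 1101 and 2301 in 18S, with log2 changes from 0.40 to 0.48. The 5′ part of 18S went the other way. Its first 7 bins, from 701 to 1050, all fell, with log2 changes from -0.47 to -0.19; these were picked out after their values were seen. With median log2 bin values set equal, 30 bins were higher and 51 lower, and bins of 25 and 100 nt gave 175 and 41 past the threshold. Scaled on spacer reads alone, the falls at 151, 51, 301, 451 and 251 were -2.31, -2.19, -1.68, -1.46 and -1.38, and those at 6701, 2551, 201 and 401 were -1.23, -0.93, -0.91 and -0.90. With a pseudocount of 100 the fall at 6751 was -1.45. On the spacer scale 4 of 30 spacer bins rose and 20 fell, and scaled on mature rRNA reads alone, 13 of 104 bins rose and 25 fell.

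Single positions numbered 3640 of 6320 past the threshold, 1710 higher and 1930 lower. In the spacers 906 of 1000 positions fell and 38 rose; in mature rRNA 1024 of 5320 fell and 1672 rose. With a minimum of 50 RPM, which leaves out many spacer positions, 1593 rose and 1087 fell, and scaled on spacer reads alone, 200 spacer positions rose and 517 fell. Scaled on mature rRNA reads alone, the majority in mature rRNA turned, with 1143 positions higher and 1274 lower. The 3 largest rises were adjacent, at 138 in ETS 1, with 1555 ± 175 RPM (log2 change 5.60, SE 0.125, limma adjusted p = 7.41e-17), at 139, with 293 ± 36.2 (log2 change 2.80), and at 137, from 45.7 ± 8.57 in WT to 376 ± 57.4 (log2 change 2.79). At 139 and 137 the log2 changes scaled on spacer reads were 4.98 and 4.89. The 3 largest falls were at 232, from 1243 ± 281 to 8.21 ± 4.31 (fell by 6.11 on the log2 scale), at 405, to 5.51 ± 1.57 (fell by 5.75), and at 102, to 30.3 ± 5.43 (fell by 5.65), and each stood on 6 to 54 reads per rpa49Δ library. Position 1031 in 18S fell by 1.26 to 769 ± 114 and 2498 rose to 3901 ± 907 (log2 change 1.40). Position 6662 fell by 1.81 to 445 ± 82.3, but had a log2 change of 0.05 when scaled on spacer reads. Position 6646 was at 2869 ± 182 (limma adjusted p = 0.0985), past the threshold only with the variance model without trend (limma adjusted p = 0.0410; from 0.0410 to 0.280 over all alternatives). In the authors' deposited table, 2071 positions were lower and 1215 higher at an unadjusted p under 0.05, of 6846 with a p-value. After Benjamini-Hochberg adjustment 1976 of these p-values were under 0.05, against 3640 positions by limma.

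**Figure D3:**
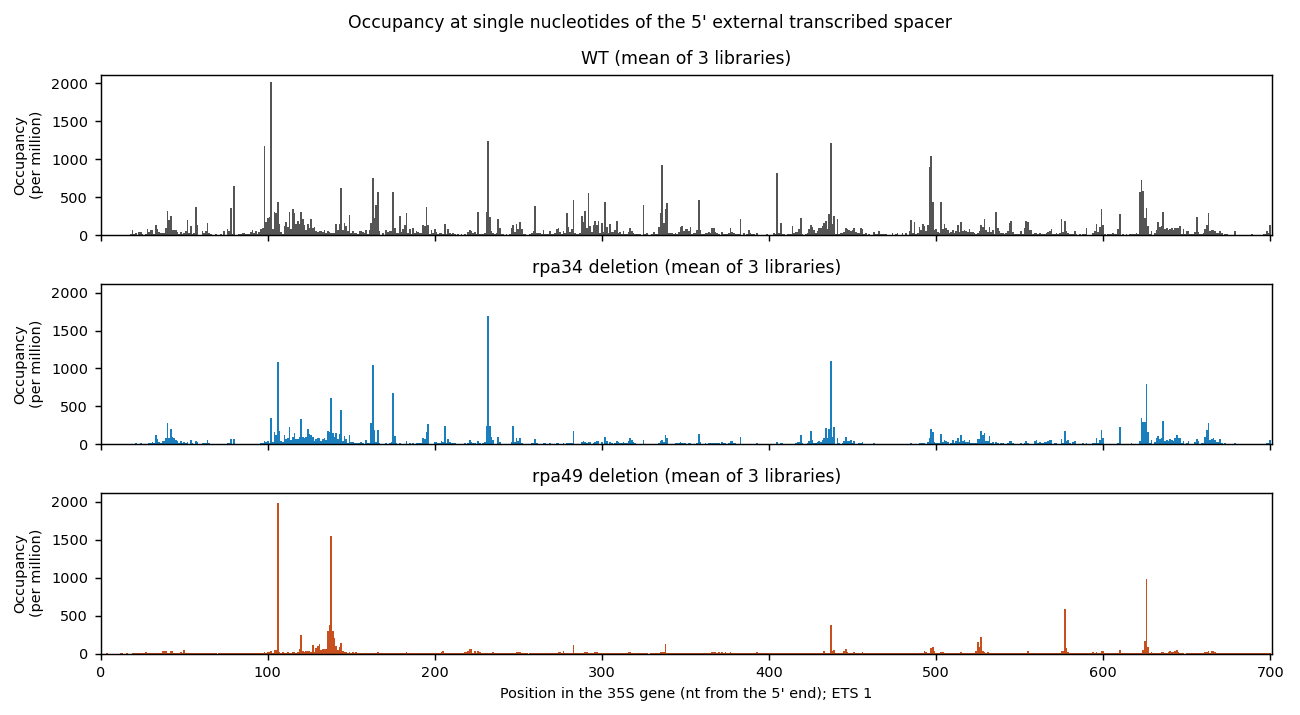
Mean occupancy of 3 libraries at each nucleotide of ETS 1 (x axis position in nt, y axis RPM, the same scale in each panel) for WT, rpa34Δ and rpa49Δ. The WT peak at 102 (2016 RPM) is at 342 in rpa34Δ and 30.3 in rpa49Δ, while position 138 goes from 22.5 to 605 and 1555.

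The deletions also differed from each other when compared directly. Relative to rpa34Δ, rpa49Δ had less of its occupancy in ETS 1 (log2 ratio of the mean shares -1.19), ITS 1 (-1.29), ITS 2 (-0.77) and ETS 2 (-1.74), and more in 18S and 25S (exact permutation p = 0.1 for each; 0.117 after adjustment). The share of 5.8S did not separate them (exact permutation p = 0.3). Occupancy within 10 nt of mature rRNA ends was 0.382 points higher in rpa49Δ (exact permutation p = 0.1), or 0.186 within 3 nt and 0.117 within 25 nt. Of 138 bins, 53 passed the threshold, 14 higher and 39 lower in rpa49Δ, and 28 of the 30 spacer bins fell. The largest falls were in ETS 1 at 151 to 200 (fell by 3.55, SE 0.147, limma adjusted p = 1.68e-08) and at bins starting at 201, 651, 1 and 401 (log2 changes -2.71, -2.20, -2.19 and -2.04). In ETS 2 the bins at 6751, 6801 and 6701 fell with log2 changes of -3.42, -2.65 and -2.15, and in ITS 1 those at 2551 and 2501 with -2.16 and -2.10. The bins at 101 in ETS 1 and 2651 in ITS 1 had log2 changes of -0.10 each (limma adjusted p = 0.390 and 0.566). The largest rises were in 25S at 5201 (log2 change 0.42, SE 0.0653, limma adjusted p = 0.000305), 5651, 4451 and 5151 and in 18S at 2451, 1101, 2301, 1851, 2151 and 2351, with log2 changes from 0.26 to 0.42. Those at 2451 and 2351 were lost with the median position of the bin (limma adjusted p = 0.0720 and 0.0888), and those at 5651 and 5151 in 2 and 5 alternatives. Leaving out bins under 1000 RPM left 33 past the threshold, 13 higher and 20 lower, and bins of 25 and 100 nt gave 116 and 27. Scaled on spacer reads alone, the falls at 201, 651, 1 and 401 were -1.57, -1.08, -1.07 and -0.89, and those at 6701, 2551 and 2501 were -1.06, -1.03 and -0.98. With a pseudocount of 100 the falls at 6751 and 6801 were -1.45 and -1.0997, and with the median position those at 151, 201 and 651 were -2.01, -1.67 and -1.37. On the spacer scale 3 spacer bins rose and 18 fell, and scaled on mature rRNA reads alone, 8 of 104 bins rose and 15 fell, against 14 and 11 of these with the whole gene as the scale.

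Between the deletions 1851 of 6083 positions passed the threshold, 663 higher and 1188 lower in rpa49Δ, or 565 and 574 with a minimum of 50 RPM. In mature rRNA 636 rose and 568 fell, but 405 rose and 611 fell when scaled on mature rRNA reads alone. The largest falls were in ETS 1. Position 232, at 1688 ± 248 RPM in rpa34Δ, fell by 6.56 on the log2 scale (SE 0.151, limma adjusted p = 8.11e-13), 163 went from 1046 ± 220 to 6.18 ± 3.92 and 175 from 680 ± 85.1 to 8.37 ± 3.96. The largest rises were at 3079 in ITS 2, from 15.1 ± 1.53 to 74.7 ± 9.94 (log2 change 1.75), at 577 in ETS 1, from 182 ± 26.9 to 586 ± 157, and at 3078 in ITS 2, from 9.06 ± 0.970 to 47.6 ± 8.94 (log2 change 1.59). Their sizes depended on pseudocount and scale. At 3079 and 3078 the log2 changes were 0.94 and 0.72 with a pseudocount of 50 and 3.41 and 3.46 scaled on spacer reads, and at 577 2.81 scaled on spacer reads. By edgeR that at 3078 was 2.40. Of the highest WT positions, 102, 1031 and 6662 were lower in rpa49Δ than in rpa34Δ (log2 changes -3.12, -0.73 and -1.35) and 2498 was higher (log2 change 0.65, limma adjusted p = 0.0120), a call lost without rpa34Δ replicate 2 or without rpa49Δ replicate 2 (limma adjusted p = 0.0730 and 0.0646; from 0.000287 to 0.0730 over all alternatives). The fall at 6662 was not past the threshold when scaled on spacer reads (limma adjusted p = 0.412).

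The bin changes of both deletions against WT were compared. Across 138 bins, which are not independent replicates, Pearson's r was 0.791 and Spearman's rho 0.849, with a covariance of 0.420. Unchanged groups, simulated against 1 shared WT group that was itself simulated, gave a mean r of 0.495 (95% of simulations from 0.297 to 0.669). Their covariance was 0.00379. Noise was drawn for each bin on its own, with a spread taken over all strains. Variation shared by neighbouring bins was left out, so the simulated ranges of r may be too narrow. Within the 30 spacer bins r was 0.453, and unchanged groups simulated for those bins gave a mean of 0.492 (95% from 0.147 to 0.743). That range holds for bins without change and so cannot say how far shared controls raised r in these changed bins. The covariance there was 0.256, against 0.00884 simulated. Within 104 mature rRNA bins r was 0.752, against a mean of 0.498 (95% from 0.237 to 0.701). Simulations for these subsets were chosen after seeing the data. Of the 29 bins that fell in rpa34Δ and the 44 that fell in rpa49Δ, 28 were shared, but 25 of these were spacer bins, where all 30 fell in rpa49Δ and sharing follows from that alone. Within mature rRNA 3 falls were shared of 4 in rpa34Δ and 14 in rpa49Δ, against 0.538 for independent lists, and 17 rises of 20 and 40, against 7.69. These lists hold on the whole-gene scale. Scaled on mature rRNA reads alone, 8 bins rose and 10 fell in rpa34Δ and 13 rose and 25 fell in rpa49Δ, and sharing was not counted on that scale. At single positions of the spacers 666 falls were shared, against 620, and in mature rRNA 587, against 151. Of the rises 25 were shared in the spacers, against 2.46, and 883 in mature rRNA, against 374. These counts by part were chosen after seeing the data. The WT libraries were too few to split, so part of the excess may come from the shared controls.

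Occupancy lay further toward the 3′ end and was less even in both deletions. The occupancy-weighted mean position was 3498 ± 38.8 nt in WT, 3655 ± 16.6 in rpa34Δ and 3725 ± 7.49 in rpa49Δ, and no groups overlapped (exact permutation p = 0.1 for each comparison, n = 3). Within mature rRNA alone the mean position was later than in WT by 66.7 nt in rpa34Δ and 73.5 nt in rpa49Δ (exact permutation p = 0.1), and the deletions differed by 6.74 nt (exact permutation p = 0.6). The Gini coefficient over positions, 0 for even occupancy, was 0.474 ± 0.00723 in WT, 0.495 ± 0.00770 in rpa34Δ and 0.538 ± 0.00427 in rpa49Δ (exact permutation p = 0.1 for each comparison). Thinned to the depth of the shallowest library, the means were 0.475, 0.496 and 0.538. Within mature rRNA alone the coefficients of WT and rpa34Δ, 0.401 ± 0.0109 and 0.407 ± 0.0105, did not separate (exact permutation p = 0.5). The highest 1% of positions held 6.95% ± 0.465 of occupancy in WT, 7.65% ± 0.257 in rpa34Δ and 8.30% ± 0.419 in rpa49Δ. Only rpa49Δ and WT did not overlap (exact permutation p = 0.1; 0.2 for rpa34Δ against WT and for the deletions against each other).

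**Figure D4:**
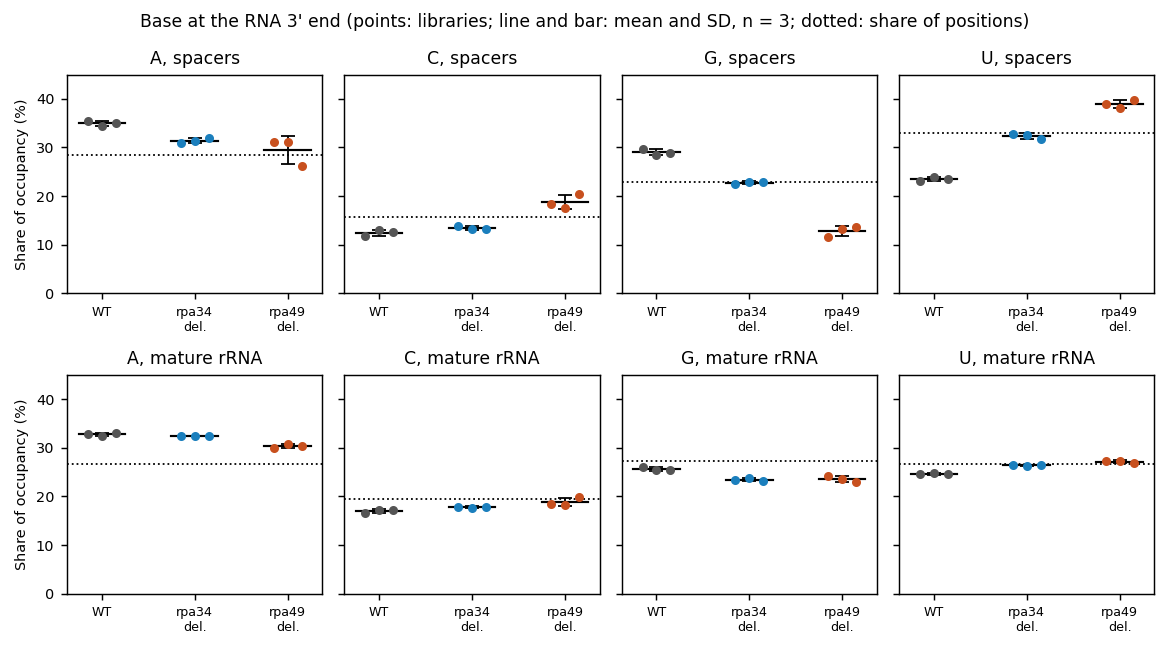
Share of occupancy, in percent, with each base at the RNA 3′ end within the spacers (top) and mature rRNA (bottom) for WT, rpa34Δ and rpa49Δ; points are libraries, lines and bars the mean and SD of 3 libraries, and dotted lines the base's share of positions. In the spacers U is at 23.5%, 32.3% and 38.9% and G at 29.0%, 22.8% and 12.8%.

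The base at the RNA 3′ end also differed between strains. Over the whole gene, where A, C, G and U make up 27.0%, 18.7%, 26.3% and 28.0% of positions, RNA ends in WT were at A for 33.0% ± 0.317 of occupancy, at G for 26.0% ± 0.392, at U for 24.5% ± 0.181 and at C for 16.5% ± 0.416. In rpa34Δ U was at 26.7% ± 0.0560, C at 17.5% ± 0.215, G at 23.4% ± 0.251 and A at 32.4% ± 0.0358. In rpa49Δ U was at 27.4% ± 0.284, C at 18.9% ± 0.830, G at 23.3% ± 0.550 and A at 30.4% ± 0.392. Against WT no groups overlapped for any of these bases (exact permutation p = 0.1; adjusted over 8 shares 0.114 for rpa34Δ and 0.1 for rpa49Δ). Between the deletions G did not separate (exact permutation p = 0.9), while A, C and U did (exact permutation p = 0.1; 0.114 adjusted). The next base in the gene was U for 27.5% ± 0.315 of WT occupancy, 25.8% ± 0.0663 in rpa34Δ and 24.7% ± 0.0769 in rpa49Δ, and A for 29.8% ± 0.326, 31.5% ± 0.311 and 32.6% ± 0.607 (exact permutation p = 0.1 for each comparison). Within the spacers the direction for A as next base turned, with differences of rpa49Δ of -0.107 points from WT and -0.243 from rpa34Δ (exact permutation p = 1.0 for each). Within the spacers alone, chosen after seeing the data, the share of U ends was 23.5% ± 0.464 in WT, 32.3% ± 0.572 in rpa34Δ and 38.9% ± 0.856 in rpa49Δ, and that of G ends 29.0% ± 0.595, 22.8% ± 0.291 and 12.8% ± 1.03 (exact permutation p = 0.1 for each comparison). There C ends were at 12.5% ± 0.614, 13.5% ± 0.357 and 18.8% ± 1.54 (exact permutation p = 0.1 for each comparison). A ends were at 34.97% ± 0.473, 31.4% ± 0.540 and 29.5% ± 2.86 (exact permutation p = 0.1 for each deletion against WT and 0.4 between the deletions). Within mature rRNA alone, also chosen after seeing the data, A ends in the rpa34Δ libraries (32.44% to 32.51%) overlapped WT (32.45% to 33.03%). The shares of C, G and U ends there did not overlap between rpa34Δ and WT.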

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

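Scaling on spacer or mature rRNA reads, edgeR and thinning were chosen after seeing the data. Region shares kept their direction in all 189 alternative values, and named bins kept direction and call in 970 of 1008 and named positions in 496 of 510. With only 3 libraries a side, no share or mean could pass a threshold, so these say little about stability. Counts of bins past the threshold were 97, 175 and 116 with 25-nt bins and 28, 41 and 27 with 100-nt bins, for rpa34Δ against WT, rpa49Δ against WT and rpa49Δ against rpa34Δ; other widths give other numbers of bins. Scaled on spacer reads, with fewer bins and positions tested, counts were 20, 24 and 21 bins and 819, 717 and 603 positions, and scaled on mature rRNA reads 18, 38 and 23 bins and 1832, 2417 and 1016 positions. For the deletions against each other, leaving out bins under 1000 RPM gave 33 and a minimum of 50 RPM 1139 positions, with fewer tested. edgeR on recovered reads called 53, 85 and 53 bins and 2731, 3614 and 1874 positions.

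With 1 library left out, bins ranged from 27 to 43, 68 to 78 and 41 to 61, and positions from 1985 to 2694, 3030 to 3657 and 1309 to 1929; the 27 came without rpa34Δ replicate 1. The correlation of bin changes ranged from 0.772 to 0.803 without a WT library, and was 0.880 with 100-nt bins, 0.849 as Spearman's rho and 0.453 in spacer bins; the cause was not tested. The median position of a bin turned the changes at 3001 to -0.50 and -1.35, where the bin spans the 3′ end of 5.8S. Scaled on spacer reads, position 6662 turned to 0.26 and 0.047, and within spacers G as next base in rpa34Δ turned to 1.54 points above WT and A as next base in rpa49Δ to -0.107 against WT and -0.243 against rpa34Δ. The difference in G ends between the deletions turned to 0.168 in mature rRNA and, with 1 library left out, ranged from -0.356 to 0.194 (0.0670 without rpa34Δ replicate 2, 0.194 without rpa49Δ replicate 3); the cause was not tested. Against WT, replicate numbers did not pair the libraries: correlations of same-numbered deviations over bins ran from -0.418 to 0.084. Between the deletions they were -0.327, 0.193 and 0.576 for replicates 1, 2 and 3, so a pairing of some libraries there stays open. With a replicate block 37, 78 and 56 bins and 2403, 3479 and 1937 positions passed. Depth limits rpa49Δ most, where 1 read is worth up to 0.805 RPM and low spacer positions stand on few reads.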

Other observations

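In the tests below, the spread of median positions over spacer bins and the U share without the highest spacer positions were set before their results were seen; all others were chosen after. In ETS 1 the remaining occupancy of rpa49Δ was concentrated at few nucleotides. The 5 highest positions of each library held 10.9% ± 0.324 of ETS 1 occupancy in WT, 17.0% ± 0.173 in rpa34Δ and 37.2% ± 2.39 in rpa49Δ, and in ITS 2 20.1% ± 1.01, 28.3% ± 1.55 and 52.1% ± 1.09, while in ITS 1 they were lower in rpa34Δ, with 17.0% ± 0.169, 13.7% ± 0.747 and 28.0% ± 1.62 (exact permutation p = 0.1 for each comparison, n = 3). Besides 138, position 106 rose from 438 ± 90.0 RPM in WT to 1083 ± 56.0 and 1983 ± 861, and 626 from 352 ± 114 to 791 ± 48.4 and 979 ± 271. Position 577 was at 193 ± 42.4 and 182 ± 26.9 in WT and rpa34Δ (limma adjusted p = 0.730) and at 586 ± 157 in rpa49Δ. Of the WT peaks, 98, 102 and 497 fell in both deletions, to 39.3, 342 and 206 RPM in rpa34Δ and 14.5, 30.3 and 68.9 in rpa49Δ. Position 437 had a log2 change of -0.12 in rpa34Δ (limma adjusted p = 0.465) and fell in rpa49Δ to 375. At 163 and 232 the log2 changes in rpa34Δ were 0.47 and 0.45 (limma adjusted p = 0.0313 for each), but the libraries of rpa34Δ and WT overlapped, and in rpa49Δ both fell, to 6.18 and 8.21 RPM.

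Past the terminator element T1 rpa49Δ stood apart, while the libraries of rpa34Δ and WT overlapped. After T1 occupancy was 583 ± 38.7 RPM in WT, 519 ± 55.5 in rpa34Δ and 31.1 ± 9.51 in rpa49Δ (exact permutation p = 0.2 for rpa34Δ and 0.1 for rpa49Δ against WT, n = 3). As a share of the reads of ETS 2 these were 10.8%, 7.07% and 7.52% in the WT libraries, 10.2%, 10.3% and 10.3% in rpa34Δ and 2.09%, 2.79% and 1.37% in rpa49Δ, the last from 25 reads with an exact 95% interval of 0.891% to 2.02%. In the residues annotated as cleaved by Rnt1 (6663 to 6697) occupancy was 1905 ± 258, 1319 ± 133 and 143 ± 22.8 RPM.

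Lower spacer and higher mature rRNA shares may come from mature rRNA that stays in the immunoprecipitate, as its reads would make up more of a library with less nascent RNA. A fragment of mature rRNA that ends in the first 9 nt of 18S, 5.8S or 25S was assumed too short to map. The shortest mapped read is not given in the sources used here. Under this assumption RNA ends in those 9 nt would change like the spacers. There occupancy was 899.6 ± 79.9 RPM in WT, 549 ± 33.5 in rpa34Δ and 99.5 ± 25.7 in rpa49Δ, log2 changes of -0.71 and -3.18, against -0.72 and -1.88 in the spacers (so further down than the spacers in rpa49Δ) and 0.11 and 0.20 in nucleotides 31 to 60. A few high positions were argued against, since without the highest 1% the spacer share still had log2 changes of -0.78 in rpa34Δ and -2.09 in rpa49Δ. Whether less nascent RNA or more carried rRNA was present stays open, as no external standard is in the tables, and an effect of the deletions on spacers themselves was not tested. As the first 9 nt of 18S, 5.8S and 25S adjoin spacers, their fall cannot tell such an effect from carried rRNA.

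Within the spacers the bins of rpa34Δ changed unequally. Single RNA ends within bins were argued against as the whole cause. The log2 changes of the median position had a spread 0.808 times that of the bin sums (SD 0.54 and 0.67), with r = 0.773 across bins. Some bins did depend on single ends. With the median position the change at 51 went from -2.48 to -1.61 and that at 401 from -0.73 to -1.34. An altered distribution of polymerases in rpa34Δ is a hypothesis that stays open, as do altered cleavage or decay of the spacers, which were not tested.

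More U and less G at the RNA 3′ end were seen within the spacers too, with C also higher and A lower. There U was 8.82 percentage points above WT in rpa34Δ and 15.4 in rpa49Δ. Mature rRNA holds no spacer sequence, so its reads could not shift shares within the spacers, whatever the values. Most reads of the whole gene lie in mature rRNA, so the spacer values do not bear on the whole-gene shift. For that shift mature rRNA reads stay open as a cause. Without the highest 5% of spacer positions the U differences were 6.68 and 12.3 points, which argues against a few high positions as the whole cause for U. The G differences went from -6.26 to -5.14 in rpa34Δ and from -16.2 to -9.08 in rpa49Δ, so a large part of the latter lay at those positions. A change in the sequences at which Pol I dwells may explain it, but base preferences of linker ligation and differences between library batches, which the labels do not give, were not tested and stay open.

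The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many calls: 51 bins and 2773 positions for rpa34Δ against WT, 86 and 3640 for rpa49Δ against WT, and 53 and 1851 for rpa49Δ against rpa34Δ, with at most 0 bins and 0 positions by limma in any other split. Each other split put libraries of both strains on both sides, so the strain difference itself entered the spread. The 0 calls there therefore say little about false calls.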
